A study of Mus musculus with 7 samples.

How the data were processed

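Bulk RNA-seq was carried out on kidneys of C57BL/6J mice aged 6 to 8 weeks, described as male in the series' design text. All 7 libraries came from animals given cisplatin, a platinum chemotherapy drug that injures kidney tubules, at 20 mg/kg into the tail vein. The labels put 4 libraries in a saline group and 3 in a group given DXZ at 40 mg/kg by the same route, 30 min before cisplatin and then every 24 h for 3 days. DXZ is used here as the labels write it, since they do not spell it out. No library without cisplatin was used here, so no value can be set against an uninjured kidney. The labels do not say that the libraries came from separate animals, and p-values therefore measure the spread between these samples. Total RNA was extracted with Trizol, per the labels.

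The deposited table of counts holds whole-number read counts per gene and library, with no normalization. The deposited FPKM table holds the same counts divided by gene length and by 1 constant per library. Those constants were 1.00 times the median-of-ratios library sizes computed from the counts, so the FPKM values are not an independent measurement. HISAT2, StringTie and the build mm9 are named, without versions or roles, in the submitters' processing notes. The gene coordinates in the deposited tables are not those of mm9: of 54495 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 53585 (98.3%) had the same start and end. Coordinates are given as in the tables and are taken as GRCm38. The program that counted reads, and whether it used strand, are not given in the sources used here. Genes with near-identical copies and antisense genes are therefore uncertain.

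Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Of 54532 genes, 27180 had a count and 15351 passed edgeR's filterByExpr. Libraries were scaled by TMM, and DXZ was compared with saline by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, at an adjusted p below 0.05 and no minimum fold. Fold changes are log2 of DXZ over saline, and each SE is the fold change divided by the square root of F. Levels are CPM, counts scaled to the TMM-adjusted library size by edgeR's cpm function. Total counts ranged from 16058157 to 18133736 per library. In 5 simulated data sets with the real means, dispersions and library sizes, each with 200 changed genes among 15351, the test recovered 47.8% of genes changed 2-fold and 80.8% of genes changed 4-fold. Of the calls, 5.30% were false. Many changes of 2-fold or less would therefore go uncalled with these samples. The simulated genes varied independently of each other, unlike those of many real lists, so 5.30% need not be the share of false calls in the real data.

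Before the data were examined, 39 gene lists were fixed from textbook knowledge. They cover nephron segments, injury, stress and metabolic pathways, and other cell types a kidney sample can hold. The 34 lists with at least 5 tested genes were tested by camera with a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. A list score is the mean log2 CPM of its members with a prior count of 2, less the mean over the 7 libraries.

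The rule for named genes was also fixed in advance. It took the 12 largest increases and the 12 largest decreases among changed genes with a mean of at least 1 CPM and no overlap between groups, leaving out predicted, clone-named and pseudogenes. It added up to 4 members of lowest adjusted p from each list past its test, in the list's direction, and up to 2 changed members of each other list. It always included 16 genes, whatever their result: Havcr1, Lcn2, Cdkn1a, Mdm2, Slc34a1, Lrp2, Top2b, Tfrc, Hmox1, Gpx4, Il6, Tnf, Ccl2, Gsdmd, Mki67 and Col1a1. Genes named outside this rule are said to be so where they appear.

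The alternatives fixed in advance were median-of-ratios size factors, no filter, a filter of 1 CPM in 3 libraries, robust dispersion estimates, limma-voom with sample quality weights, DESeq2 1.42.0, a test against a fold of 1.5, and limma on log2 of FPKM plus 1 or plus 0.1, filtered at an FPKM of 1 or unfiltered. Each library was also left out in turn, and the replicate number was used as a block. A pair of alternatives was chosen after seeing the data: saline 1 and DXZ 1 both left out, and each library's trend with gene length and GC content removed by splines. GC content was known for 15339 (99.9%) of the tested genes. Replicate libraries differed by 15.1 to 99.1 times the sampling noise (chi-square per degree of freedom), so none was a copy of another.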

Results

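The transcriptomes of 7 kidney libraries from cisplatin-treated mice were compared, 4 labelled saline and 3 labelled DXZ. Total counts were 18133736, 16400460, 16058157 and 17776643 in saline 1 to 4, and 16243682, 16967701 and 17498520 in DXZ 1 to 3. Between 20803 and 21827 genes were detected per library, and mitochondrial transcripts made up 5.18% to 8.35% of counts. The comparison asks, per the series' design text, which genes differ between the 2 groups.

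Kidneys labelled DXZ had lower levels of proximal tubule transcripts and higher levels of tubule injury transcripts than kidneys labelled saline. Both lists passed camera with its preset correlation but not with an estimated one (camera adjusted p = 0.355 for both). The injury markers Havcr1 and Lcn2 did not pass singly. Slc34a1, the main phosphate transporter of the proximal tubule, fell from 2489 ± 1300 CPM (SD, n = 4) to 338 ± 200 CPM (SD, n = 3). Lrp2, which encodes the endocytic receptor megalin, fell from 772 ± 280 to 248 ± 25.7 CPM. Krt8, an epithelial keratin, rose from 230 ± 41.3 to 529 ± 72.3 CPM, and Hmox1, the heme-degrading enzyme, rose from 110 ± 14.3 to 201 ± 41.0 CPM. By edgeR's quasi-likelihood test 853 of 15351 genes changed, 498 higher and 355 lower in DXZ, with a lowest adjusted p of 0.0138, and 343 of them changed by more than 2-fold. At an unadjusted p under 0.05 there were 3899 genes, where chance gives 768. The groups did not overlap for any of the 853, nor for 3700 (24.1%) of all tested genes, where chance gives 5.71%.

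The count of changed genes rested on single libraries. It was 374, 296, 426 and 4 without saline 1, 2, 3 and 4, and 1574, 1 and 141 without DXZ 1, 2 and 3; with saline 1 and DXZ 1 both left out, an alternative chosen after seeing the data, it was 1332. Of the 66 named genes that passed, 66 lost their call without DXZ 2 and 64 without saline 4. The other 2, Pvalb and Adgrg4, had too few counts to test without saline 4. At an unadjusted p under 0.05 by edgeR's test there were 3074 genes without saline 4 and 3191 without DXZ 2, against 3899 with all libraries. Against a minimum fold of 1.5, edgeR called 3 genes, 0 higher and 3 lower, while 556 higher and 450 lower had an unadjusted p under 0.05; without a minimum fold DESeq2 called 1114 higher and 913 lower.

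**Figure D1:**
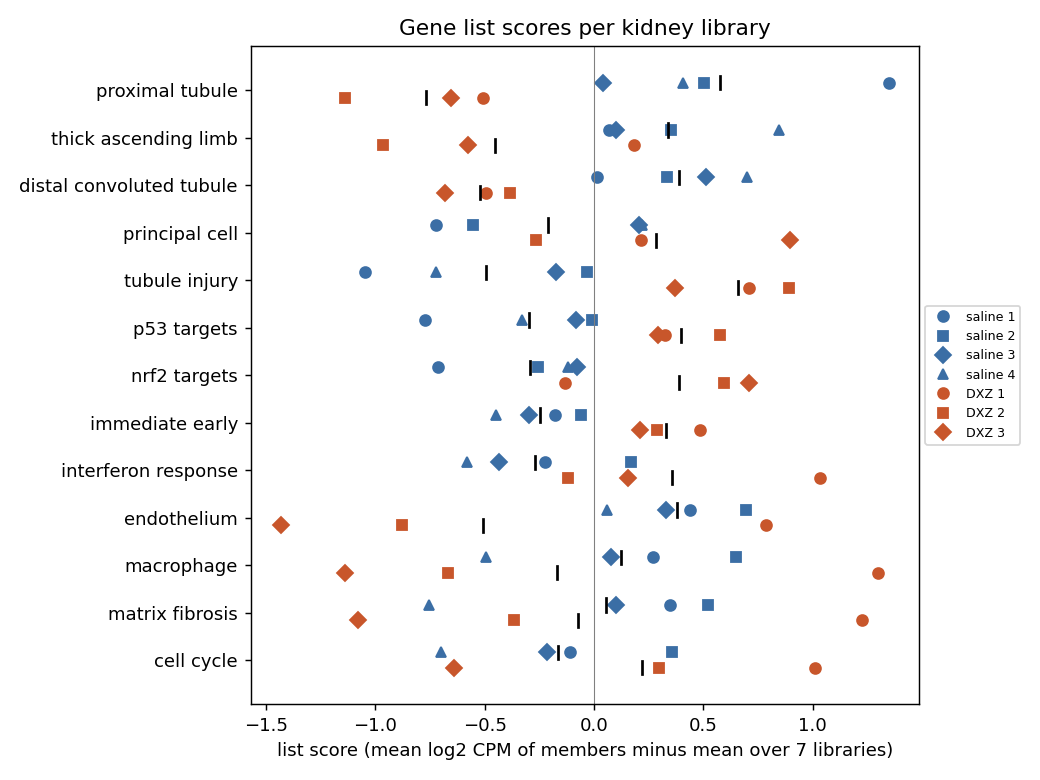
List scores (horizontal axis, mean log2 CPM of a list's members less the mean over the 7 libraries) for 13 gene lists, with 1 point per library, saline in blue and DXZ in orange, and black bars at group means. Proximal tubule scores lie between 0.043 and 1.35 in saline and between -1.14 and -0.51 in DXZ, while the macrophage score of DXZ 1 (1.30) lies apart from those of DXZ 2 (-0.67) and DXZ 3 (-1.14).

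Of 38 proximal tubule genes tested, 12 fell and 0 rose, or 29 and 0 adjusted over the list alone, with a median log2 fold change of -1.16 (camera adjusted p = 2.13e-20; adjusted p = 0.355 with an estimated correlation). Slc7a7, a basolateral amino acid transporter (chromosome 14, 54369442 to 54417780, GRCm38), fell from 148 ± 48.4 to 31.8 ± 7.58 CPM (log2 fold change -2.22, SE 0.28, edgeR adjusted p = 0.0204). Slc5a12, a lactate transporter, had a log2 fold change of -2.13, and Slc17a1, a phosphate and urate transporter, of -1.13 (edgeR adjusted p = 0.0209 and 0.0204). Slc34a1 had a log2 fold change of -2.88 (SE 0.59, edgeR adjusted p = 0.0373) and Lrp2 of -1.64 (SE 0.27, edgeR adjusted p = 0.0234). With the preset correlation of 0.01 the list kept its call whichever single library was left out. The correlation estimated for this list was 0.40.

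Of 25 tubule injury genes, 8 rose and 0 fell, or 18 and 0 adjusted over the list alone, with a median log2 fold change of 1.17 (camera adjusted p = 6.91e-15; adjusted p = 0.355 with an estimated correlation). Krt18 had a log2 fold change of 1.47 (SE 0.21), Krt8 of 1.20 (SE 0.17) and Lgals3, encoding galectin-3, of 0.85 (SE 0.15), and Plaur, the urokinase receptor, rose from 18.2 ± 5.54 to 51.4 ± 9.65 CPM, with edgeR adjusted p-values between 0.0204 and 0.0292. The commonly used injury markers did not pass: Havcr1, encoding KIM-1, was at 316 ± 317 CPM in saline and 1007 ± 393 in DXZ (log2 fold change 1.67, SE 0.75, edgeR adjusted p = 0.207), and Lcn2, encoding NGAL, at 568 ± 542 and 2305 ± 1194 CPM (2.02, SE 0.76, edgeR adjusted p = 0.145). Their saline libraries overlapped the DXZ libraries. Havcr1 was at 2.59 without saline 2 and did not pass.

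**Figure D2:**
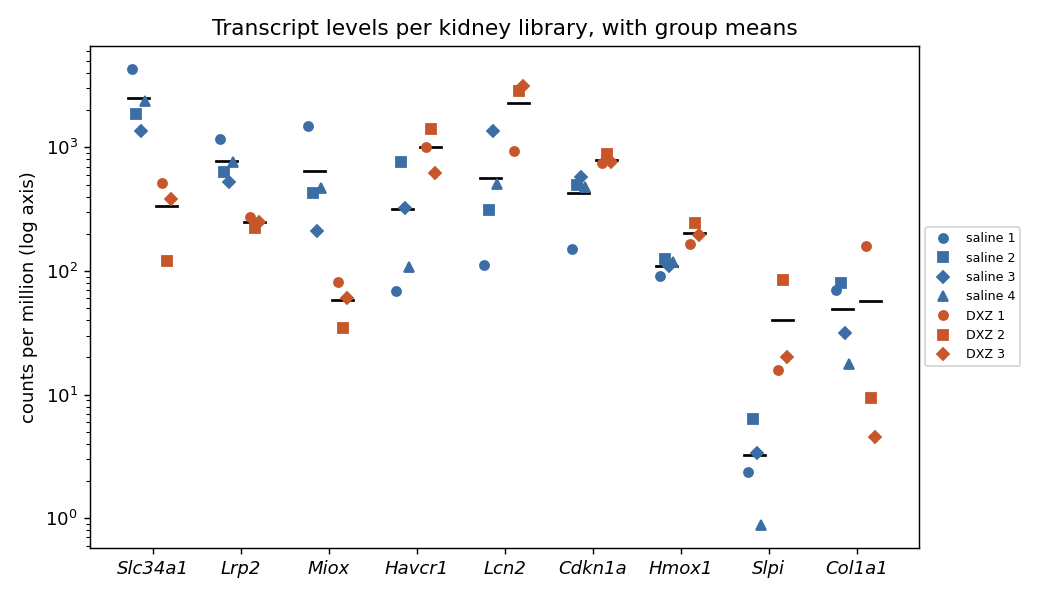
CPM (log vertical axis) of 9 named genes in each library, saline in blue and DXZ in orange, with black bars at group means. Slc34a1, Lrp2 and Miox are lower in all 3 DXZ libraries than in all 4 saline libraries, Hmox1 and Slpi are higher in all 3, and Havcr1, Lcn2 and Col1a1 overlap.

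Of 7 distal convoluted tubule genes 2 fell, or 2 adjusted over the list alone, and the median log2 fold change was -0.55 (camera adjusted p = 0.000318; adjusted p = 0.304 with an estimated correlation). Slc12a3, the thiazide-sensitive sodium chloride cotransporter, fell from 215.8 ± 35.01 to 71.9 ± 11.1 CPM (log2 fold change -1.59, SE 0.16, edgeR adjusted p = 0.0192). Pvalb, encoding parvalbumin, fell from 91 to 3 counts in all (edgeR adjusted p = 0.0333), a ratio of 23.0 with a 95% exact counting interval of 7.61 to 113 that covers counting error only. Its saline libraries lay between 0.57 and 2.44 CPM. Trpv5 (log2 fold change -0.64, edgeR adjusted p = 0.186) and Wnk4 (-0.17, edgeR adjusted p = 0.361) did not pass. Trpv5 was at -0.40 without DXZ 3 and Wnk4 at -0.10 without DXZ 1. The list's median was -0.27 without saline 3 and -0.30 without saline 4.

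Of 10 thick ascending limb genes 1 fell, or 4 adjusted over the list alone, with a median log2 fold change of -0.57 (camera adjusted p = 0.00208; adjusted p = 0.745 with an estimated correlation). Egf, made mainly in this segment and the distal tubule, fell from 292 ± 135 to 49.1 ± 31.3 CPM (log2 fold change -2.57, edgeR adjusted p = 0.0390). Slc12a1, the loop diuretic target, had a log2 fold change of -0.99 (edgeR adjusted p = 0.0947), Tmem207 of -1.29 and Cldn10 of -0.56, and none of these 3 passed. Without DXZ 1 they were at -1.30, -1.97 and -0.75 and passed (edgeR adjusted p = 0.0420, 0.0187 and 0.0415). The list's median was -0.92 without DXZ 1. Principal cell genes had a median log2 fold change of 0.53 over 8 tested genes and did not pass (camera adjusted p = 0.271), but 1 member, Fxyd4, rose from 30.5 ± 6.75 to 75.7 ± 27.8 CPM (edgeR adjusted p = 0.0338). The list's median was 0.05 without DXZ 3 (camera adjusted p = 0.680), 0.73 without DXZ 2, where it passed (0.0189), and 0.70 with the replicate block, where it passed too (0.00108). Intercalated cell genes had a median of -0.02 with 0 of 9 changed (camera adjusted p = 0.945). Of 12 podocyte genes 0 changed by either adjustment, over all genes or adjusted over the list alone, at a median of -0.39 (camera adjusted p = 0.0194; adjusted p = 0.745 with an estimated correlation). Thsd7a was at -0.72, Ptpro at -0.66, Clic3 at -1.10 and Nphs1 at -0.52, none past its test. Without DXZ 1, Thsd7a (-0.94), Ptpro (-0.90) and Clic3 (-1.77) passed (edgeR adjusted p between 0.0177 and 0.0298). The podocyte call was lost without saline 3 (camera adjusted p = 0.0533), saline 4 (0.0772) or DXZ 3 (0.0851), or with the replicate block (0.108).

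The p53, NRF2 and immediate early lists were higher in DXZ. Of 30 p53 targets 4 rose, or 17 adjusted over the list alone, and all 30 had a positive log2 fold change, with a median of 0.69 (camera adjusted p = 2.40e-11; adjusted p = 0.563 with an estimated correlation). Btg2, an antiproliferative gene, rose from 170 ± 34.96 to 381 ± 52.1 CPM, Gdf15, a stress cytokine, from 163 ± 23.7 to 395 ± 115 CPM, and Aen and Psrc1 also rose (edgeR adjusted p between 0.0215 and 0.0446). Cdkn1a, encoding p21, was at 427 ± 188 and 797 ± 79.8 CPM (log2 fold change 0.90, edgeR adjusted p = 0.189) and Mdm2 at 142 ± 24.3 and 200 ± 35.5 CPM (0.49, edgeR adjusted p = 0.116). Of 23 NRF2 targets, which answer oxidative stress, 5 rose, or 9 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 2.15e-06; adjusted p = 0.745 with an estimated correlation). Srxn1 rose from 241 ± 70.2 to 787 ± 334 CPM and Txnrd1 from 379 ± 5.21 to 623 ± 55.4 CPM, and G6pdx and Hmox1 had log2 fold changes of 0.75 and 0.87 (edgeR adjusted p between 0.0209 and 0.0370). The NRF2 score was -0.13 in DXZ 1, within the saline range of -0.71 to -0.08, and 0.59 and 0.71 in DXZ 2 and DXZ 3. Of 15 immediate early genes 2 rose, or 9 adjusted over the list alone, with a median of 0.57 (camera adjusted p = 8.54e-05; adjusted p = 0.195 with an estimated correlation). Fosl1 had a log2 fold change of 1.96 and Ier2 of 0.78 (edgeR adjusted p = 0.0353 and 0.0333), while Jund at 0.61 and Klf6 at 0.72 did not pass. Without DXZ 1 both passed, at 0.73 and 0.89 (edgeR adjusted p = 0.0297 and 0.0234).

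Interferon response genes were higher as a list, with a median log2 fold change of 0.71 and all 28 tested members positive, although 0 passed singly and 10 did adjusted over the list alone (camera adjusted p = 3.27e-06; adjusted p = 0.745 with an estimated correlation). Ifit1 was at 0.83, Oasl1 at 1.31, Gbp2 at 0.91 and Irf7 at 1.30, with edgeR adjusted p-values between 0.0510 and 0.0623. Ifit1 passed without DXZ 1 (0.56, edgeR adjusted p = 0.0498) and Oasl1 without saline 2 (1.62, 0.0393), and Irf7 was at 0.78 without DXZ 1. The list score was 1.04 in DXZ 1, -0.12 in DXZ 2 and 0.16 in DXZ 3, and the median was 0.27 without DXZ 1. Saline scores ran from -0.58 to 0.17, so only DXZ 1 lay outside the saline range. Cell cycle genes had a median of 0.52, with 0 of 35 changed by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0194; adjusted p = 0.856 with an estimated correlation). Their score was 1.01 in DXZ 1, 0.30 in DXZ 2 and -0.64 in DXZ 3, the last 2 within the saline range of -0.70 to 0.36. The call was lost without DXZ 1 (median 0.06, camera adjusted p = 0.719), DXZ 2 (0.0501), saline 4 (0.0986) or saline 1 and DXZ 1 both (0.682), with the replicate block (0.134) and by voom (0.283). The median was 0.82 without DXZ 3. Pcna was at 0.35, Rrm2 at 1.12, Mcm2 at 0.44, Ccne1 at 1.07 and Mki67 at 0.94, none past its test. Rrm2 passed without saline 2 (1.49, edgeR adjusted p = 0.0482), and Mki67 was at -0.15 without DXZ 1 and 1.42 without DXZ 3.

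Endothelial genes had a median log2 fold change of -0.61, with 0 of 12 changed by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.856 with an estimated correlation). Tek was at -0.82, Ehd3 at -0.65, Cdh5 at -0.61 and Egfl7 at -0.51, none past its test. Without DXZ 1 they were at -1.99, -1.40, -1.34 and -1.11 and passed (edgeR adjusted p between 0.0185 and 0.0250), and without DXZ 3 at -0.44, -0.36, -0.27 and -0.22. Without DXZ 2 Tek was at -0.54. Their score was 0.78 in DXZ 1, -0.88 in DXZ 2 and -1.43 in DXZ 3. The median was -1.45 without DXZ 1, and the call was lost without DXZ 2 (median -0.39, camera adjusted p = 0.0548) or DXZ 3 (-0.23, 0.149). Macrophage genes had a median near 0 (0.0045) over 17 genes (camera adjusted p = 0.944), but their scores were 1.30, -0.67 and -1.14 in DXZ 1, 2 and 3, and without DXZ 1 the median was -1.33 (camera adjusted p = 0.000268). A pair of its members rose, Cd68, a lysosomal glycoprotein, from 11.5 ± 4.23 to 43.2 ± 12.6 CPM and Cd14, the endotoxin co-receptor, from 33.3 ± 5.92 to 62.1 ± 7.42 CPM (edgeR adjusted p = 0.0215 and 0.0275). Matrix genes had a median of 0.05 over 22 genes (camera adjusted p = 0.638), of -1.35 without DXZ 1 (camera adjusted p = 0.0238) and of 0.51 without DXZ 3 (0.0182). Mmp14, a membrane-bound metalloproteinase, rose with a log2 fold change of 0.75 (edgeR adjusted p = 0.0267). Col1a1, the main collagen of scar tissue, was at 49.7 ± 30.0 and 57.3 ± 87.2 CPM (log2 fold change 0.21, edgeR adjusted p = 0.929), and at a log2 fold change of -2.83 without DXZ 1 (edgeR adjusted p = 0.0464). Pericyte and smooth muscle genes had a median of -0.25 over 10 genes (camera adjusted p = 0.0782), and of -0.76 without DXZ 1, where the list passed (camera adjusted p = 1.71e-06). Its median was -0.09 without DXZ 2 (0.370) and -0.14 without DXZ 3 (0.183). It also passed by voom (0.00617), with no filter (0.0184), with the replicate block (0.0194), with length and GC trends removed (0.0329) and without saline 1 and DXZ 1 (1.52e-06), the last 2 chosen after seeing the data.

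Of 20 glycolysis and hypoxia genes 3 rose, or 4 adjusted over the list alone, at a median log2 fold change of 0.09 (camera adjusted p = 0.0315; adjusted p = 0.745 with an estimated correlation). Adm, encoding adrenomedullin, rose from 13.5 ± 2.25 to 38.3 ± 9.95 CPM, and Hk2, a hexokinase, and Slc2a1, a glucose transporter, had log2 fold changes of 1.83 and 1.04 (edgeR adjusted p = 0.0204, 0.0314 and 0.0316), and Pkm was at 0.71 and did not pass. The call was lost without saline 1 (camera adjusted p = 0.0708), saline 3 (0.0621) or DXZ 3 (median 0.06, 0.0978), and by voom (0.117). The median was 0.19 without saline 4 and 0.16 without DXZ 1. Of 20 cholesterol synthesis genes 2 fell, or 2 adjusted over the list alone, at a median of -0.19 (camera adjusted p = 0.0304; adjusted p = 0.856 with an estimated correlation). Stard4 and Nsdhl had log2 fold changes of -0.77 and -0.58 (edgeR adjusted p = 0.0294 and 0.0444), and Sqle at -0.58 and Lss at -0.46 did not pass. Without DXZ 1 Sqle was at -0.81 and passed (edgeR adjusted p = 0.0187). The call was lost without saline 1 (median -0.06, camera adjusted p = 0.262), DXZ 2 (-0.13, 0.0654), DXZ 3 (0.0676) or saline 1 and DXZ 1 both (0.123), and by voom (0.101). The median was -0.41 without DXZ 1. Fatty acid oxidation genes had a median of -0.13 with 0 of 33 changed (camera adjusted p = 0.267). The median was -0.29 without DXZ 3, where the list passed (0.00754), -0.20 without saline 2 (0.0621), and -0.03 without DXZ 1 (0.609) or saline 4 (0.877). Oxidative phosphorylation genes had a median of -0.02 with 1 of 32 changed, Ndufs1 at -0.67 (camera adjusted p = 0.523).

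Members of other lists also changed although the lists did not pass. Ripk3 and Mlkl, which act in necroptosis, rose with log2 fold changes of 1.46 and 1.67 (edgeR adjusted p = 0.0313 for both). The lytic cell death list that holds them had a median of 0.30 over 14 genes (camera adjusted p = 0.0732), with 3 members higher and 1 lower. Atf3 and Ppp1r15a rose in the unfolded protein and integrated stress list (1.05 and 0.97; list median 0.30 over 21 genes, camera adjusted p = 0.104), and Hspb1 rose in the heat shock list (1.64; median 0.18 over 14 genes, camera adjusted p = 0.487). Gch1 rose in the ferroptosis and glutathione list (1.34; median 0.13 over 24 genes, camera adjusted p = 0.196). Slc39a8, a metal transporter, fell in the iron handling list (-0.82; median 0.06 over 23 genes, camera adjusted p = 0.909), and Hlf, a clock output factor, fell in the circadian list (-1.42; median -0.05 over 17 genes, camera adjusted p = 0.482). Birc3 and Il34 rose in the cytokine, chemokine and NF-kB list (0.69 and 0.89; median 0.26 over 25 genes, camera adjusted p = 0.225). By edgeR's test these 8 genes had adjusted p-values between 0.0238 and 0.0447. The lytic cell death list passed without saline 2 (median 0.34, camera adjusted p = 0.0302) or DXZ 3 (0.46, 0.0182), and with length and GC trends removed (0.28, 0.0441), and had a median of 0.09 without DXZ 1. The unfolded protein and integrated stress list passed without saline 4 (median 0.29, camera adjusted p = 0.0475) and with the replicate block (0.29, 0.0310), and had a median of 0.14 without DXZ 2, 0.17 without saline 1 and 0.18 without saline 2. The ferroptosis and glutathione list passed without DXZ 1 (0.27, 0.00734) and without saline 1 and DXZ 1 (0.29, 0.0108), and had a median of 0.05 without DXZ 3. The cytokine, chemokine and NF-kB list passed without saline 1 (median 0.24, camera adjusted p = 0.0433), saline 2 (0.44, 0.00287) or DXZ 3 (0.33, 0.0464), and its median was -0.19 without DXZ 1. Gpx4 was at -0.14, Tfrc at 0.30, Top2b at 0.15, Gsdmd at 0.12 and Ccl2 at -0.34, with edgeR adjusted p-values between 0.270 and 0.887. Top2b was at 0.03 without DXZ 2. Leaving out 1 library, Gpx4 ranged from -0.24 (without DXZ 3) to -0.02 (without DXZ 1), Gsdmd from -0.24 (without DXZ 1) to 0.33 (without DXZ 3) and Ccl2 from -2.22 (without DXZ 1) to 0.996 (without saline 2), and none passed. Il6 and Tnf had too few counts to test, with at most 8 and 16 counts in any library.

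The remaining lists did not pass with all libraries. Median log2 fold changes were 0.85 for metal response (5 genes, camera adjusted p = 0.196), 0.60 for neutrophil genes (7 genes, 0.271), 0.05 for acute phase and complement (19 genes, 0.523) and 0.07 for topoisomerases (7 genes, 0.682). They were -0.40 for adipocyte genes (9 genes, camera adjusted p = 0.477), -1.10 for B cell genes (5 genes, 0.945) and -0.04 for mitochondrially encoded genes (13 genes, 0.945). The neutrophil median was 0.02 without DXZ 1 (camera adjusted p = 0.784) and 0.98 without DXZ 3, where the list passed (0.0377). The B cell median was -3.32, -0.57 and -0.67 without DXZ 1, 2 and 3, and the list did not pass in these fits. The test's direction was opposite to the median's sign for the adipocyte, B cell, topoisomerase, iron handling and intercalated cell lists. The mean was also opposite to the median for the adipocyte list (0.08) and the mitochondrially encoded list (0.14). With fewer than 5 tested genes, no list test was made for T and NK cell (4 tested), erythroid (2), skeletal muscle (2), adrenal (1) and exocrine pancreas (0) genes, and 0 of these genes changed over all genes tested.

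The largest single increases began with Crct1. This gene of the epidermal differentiation complex on chromosome 3 rose from 1.87 ± 0.951 to 31.6 ± 19.0 CPM (log2 fold change 4.08, SE 0.56, edgeR adjusted p = 0.0204). Sprr2f, a cornified envelope precursor in the same complex, had a log2 fold change of 3.85 (SE 0.67), and Ivl, encoding involucrin, of 2.53 (SE 0.51). Slpi, a secreted protease inhibitor, rose from 3.22 ± 2.29 to 40.3 ± 38.9 CPM (3.64, SE 0.75). Calcb (3.39), Cst6 (3.39), Flnc (3.15), Nrcam (2.93), Slc6a19os (2.87), Meltf (2.82), Ptprn (2.74) and Hcn3 (2.59) made up the rest of the 12, with edgeR adjusted p-values between 0.0204 and 0.0446. Slc6a19os is antisense to a proximal tubule transporter gene, and its reads cannot be told from those of its partner without strand. Sprr2f has close paralogs and is uncertain for that reason.

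The 12 largest decreases included several enzymes and transporters. Miox, encoding myo-inositol oxygenase, fell from 650 ± 572 to 58.7 ± 23.4 CPM (log2 fold change -3.47, SE 0.70, edgeR adjusted p = 0.0362), and Inmt, an indole methyltransferase, from 136 ± 129 to 8.34 ± 1.83 CPM (-4.03, SE 0.77, edgeR adjusted p = 0.0313). Slc7a12, an amino acid transporter, had a log2 fold change of -4.27 and Fam151a of -3.12 (edgeR adjusted p = 0.0223 and 0.0390). Adgrg4 fell from 119 to 2 counts in all (edgeR adjusted p = 0.0440), a ratio of 45.0 with a 95% exact counting interval of 12.2 to 376 that covers counting error only. Slc22a29 (-3.73), Ugt2b37 (-3.60), Hsd3b4 (-3.49), Cyp2d12 (-3.34), Nat8f7 (-4.16), Nat8f6 (-3.53) and Nat8f3 (-3.13) belong to families of near-identical genes, so their single values are uncertain (edgeR adjusted p between 0.0204 and 0.0447).

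In the 18 lists where genes were tested and edgeR's test called 0 of them, the counts at an unadjusted p under 0.05 and by DESeq2 were 11 and 10 for interferon response, 5 and 1 for cell cycle, 4 and 3 for podocyte, 3 and 1 for fatty acid oxidation, 3 and 2 for acute phase and complement, 2 and 1 for each of the intercalated cell and metal response lists, 1 and 1 for pericyte and smooth muscle, 1 and 0 for each of the adipocyte, topoisomerase, mitochondrially encoded and adrenal lists, and 0 and 0 for each of the endothelial, neutrophil, B cell, erythroid, skeletal muscle and T and NK cell lists. With an estimated correlation 0 of the 13 list calls held, and 4 lists had an unadjusted camera p under 0.05. By fry, which asks whether a list's genes move one way and does not compare it with other genes, 2 passed, immediate early (adjusted p = 0.00289) and distal convoluted tubule (adjusted p = 0.0459).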

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

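Among 143 values of the 4 saline libraries (34 list scores, 6 library measures and 103 genes on a log2 scale), 5 had 1 library far from the other 3 by Dixon's test, all of them genes, where chance alone gives about 1 in 20. Groups of 3 were not tested. Cdkn1a was at 152 CPM in saline 1, below the other saline libraries. G6pdx was at 41.3 CPM in saline 1, Mlkl at 6.54 CPM in saline 2, Lss at 15.3 CPM in saline 2 and Hk2 at 1.35 CPM in saline 4.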

How the results depend on the processing

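The fits without saline 1 and DXZ 1 together and with length and GC trends removed were chosen after seeing the data. None of the 66 named genes and 13 lists that passed changed direction in any fit. For the genes this was nearly fixed in advance, since the groups did not overlap for any of the 853 changed genes. Scaling, filter, robust estimates, voom, and FPKM plus 1 or 0.1 with a filter gave 824 to 983 changed genes against 853. The count was 2027 with DESeq2, 559 with length and GC trends removed, 1332 without saline 1 and DXZ 1, 145 with unfiltered FPKM plus 1, and 3 against a fold of 1.5; leaving out 1 library gave 1 to 1574. With camera's preset correlation 11 to 17 lists passed of the 32 to 38 that each fit could test; of 34 lists, 0 passed with an estimated correlation and 2 by fry. The cause was not tested for any of these.

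Whether the replicate numbers pair the samples is not settled by the values: correlations of same-numbered deviations were 0.26, -0.09 and 0.23, and saline 2 correlated best with DXZ 1 (0.43). With the replicate number as a block, which leaves out saline 4, 115 genes and 14 lists passed, against 4 genes in the unblocked fit without saline 4.

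Signs turned 63 times, 19 for 5 genes and 44 for 12 lists, none of which had passed with all libraries. With the replicate block, medians were 0.021 for intercalated cell, -0.77 for macrophage, -0.76 for matrix and -0.016 for topoisomerase genes, and log2 fold changes were -0.14 for Gsdmd and -1.62 for Col1a1. With voom, medians were 0.90 for adipocyte, 0.096 for circadian clock, -0.83 for macrophage, -0.62 for matrix and 0.060 for mitochondrially encoded genes, and Col1a1 was at -1.65. The macrophage median was -0.0077 with median-of-ratios scaling, -0.018 without a filter and -0.12 with length and GC trends removed; that of matrix genes was -0.0025 without a filter and -0.028 with the trends removed, where Col1a1 was at -0.010. Col1a1 was at -0.69 with FPKM plus 1, filtered or not, and at -1.08 with FPKM plus 0.1. Without saline 1 and DXZ 1, medians were -0.020 for acute phase, 0.64 for adipocyte, 0.14 for circadian clock, 0.073 for intercalated cell, -1.18 for macrophage, -1.20 for matrix, 0.24 for mitochondrially encoded, -0.19 for neutrophil, 0.022 for oxidative phosphorylation and -0.085 for topoisomerase genes; Mki67 was at -0.13, Gpx4 at 0.0092, Gsdmd at -0.15 and Col1a1 at -2.62.

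Leaving out 1 library, the median ranged from -0.099 to 0.30 for acute phase, -0.92 to 0.42 for adipocyte, -0.14 to 0.018 for circadian clock, -0.19 to 0.44 for cytokine, -0.11 to 0.15 for intercalated cell, -0.044 to 0.12 for iron handling, -1.33 to 0.47 for macrophage, -1.35 to 0.51 for matrix, -0.21 to 0.16 for mitochondrially encoded, -0.072 to 0.029 for oxidative phosphorylation and -0.21 to 0.13 for topoisomerase genes. Mki67 ranged from -0.15 to 1.42, Gsdmd from -0.24 to 0.33, Ccl2 from -2.22 to 0.996 and Col1a1 from -2.83 to 0.73. Of these turned values, the macrophage and matrix lists and Col1a1 without DXZ 1, and the adipocyte, macrophage, matrix and mitochondrially encoded lists without saline 1 and DXZ 1, passed their tests. Among the other values, named genes that had passed lost their call 397 times and lists 45 times, and genes and lists that had not passed gained one 65 and 21 times. Depth limits what was tested: Il6 and Tnf had too few counts, and some fits gave no value for 12 named genes (33 values) and for the B cell and metal response lists (8 values), which their filters left out.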

Other observations

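The tests of sample composition, of length and GC content, of exchanged libraries, of sequencing depth, of stromal tissue and of urothelium, and the 20 gene families, were chosen after the results were seen. Those of other splits were written before. Krt20 and the urothelial genes other than Ivl fall outside the naming rule and were chosen after their values were seen.

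Ribosomal protein genes held more increases than expected, although most members did not pass. Of 81 Rpl and Rps genes tested, 26 were higher in DXZ and 0 lower, where 2.63 were expected to be higher (Fisher's exact test, adjusted p = 8.82e-18 over 20 families in both directions), with a median log2 fold change of 0.46. With median-of-ratios scaling the count was 24, and with length and GC trends removed it was 14 at a median of 0.39. It was 9, 6, 12 and 0 without saline 1, 2, 3 and 4, and 33, 0 and 0 without DXZ 1, 2 and 3, while the median stayed between 0.37 and 0.54 in these fits. These genes have many processed pseudogenes, so single members are uncertain. Keratin genes had 3 of 12 higher, Krt8, Krt18 and Krt20 (Fisher's exact test, adjusted p = 0.0400), and 0 without saline 4 or without DXZ 2. All 3 are members of the tubule injury list, so this count is not independent of that list's result. In every family, Fisher's test treats genes as independent, so its p-values do not measure the spread between samples. The expected counts do not allow for expression level.

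The Slc22, Cyp2 and Ugt families held more decreases than expected, although most members did not pass. Their counts include Slc22a29, Cyp2d12 and Ugt2b37, named above among the 12 largest decreases, so they are not independent of those results. The Slc22 count also includes Slc22a8, a member of the proximal tubule list. Of 22 Slc22 organic ion transporter genes 5 were lower where 0.509 were expected (Fisher's exact test, adjusted p = 0.00122), of 20 Cyp2 cytochrome P450 genes 5 (0.463 expected, adjusted p = 0.000998), and of 14 Ugt genes 4 (0.324 expected, adjusted p = 0.00187). Without saline 4 or without DXZ 2, in fits that called 4 and 1 genes in all, these counts were 0. For the Ugt genes they were also 0 without saline 2 or DXZ 3 and 2 without each of the other libraries, the Cyp2 count was 3 without saline 2 and 2 without DXZ 3, and the Slc22 count 3 and 1. With length and GC trends removed the Slc22, Cyp2 and Ugt counts were 4, 4 and 2. Medians were -1.04, -0.71 and -0.57, and 0 or 1 members of each family rose. Without saline 4 the Slc22, Cyp2 and Ugt medians were -1.02, -0.86 and -0.59. Without saline 1 the Slc22 and Cyp2 medians were -0.62 and -0.27, without DXZ 2 the Cyp2 median was -0.40, and without DXZ 3 the Ugt median was -1.30. Of other families, Cyp4 genes had 0 lower and 1 higher of 14 at a median of -0.01, Gst genes 0 lower of 20 at a median of 0.18, Aldh genes 2 lower of 20 at -0.28 (0.463 expected, adjusted p = 0.257) and Hsd genes 1 lower of 13 at -0.36 (0.301 expected, adjusted p = 0.630). No test compared these families with the Slc22, Cyp2 and Ugt families. Zinc finger genes of the Zfp family had 0 higher and 1 lower of 318, where 10.3 and 7.35 were expected (adjusted p = 0.000807 and 0.0445). Without DXZ 1 the Zfp counts were 4 higher and 4 lower of 319, and with length and GC trends removed 0 and 0 of 318.

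Other splits of the samples bear differently on genes and on lists. Of the 35 splits of the 7 libraries into 4 and 3, 1, the real one, gave as many as 853 changed genes, and the highest other gave 6. A share of 1 in 35 is the smallest that this test can give. It argues against chance for the count of genes but does not exclude it. The count also fell to 4 without saline 4 and to 1 without DXZ 2. For lists, 22 of the 35 splits gave as many as the 13 of the real split, and the highest other gave 21, so chance cannot be excluded for the count of lists under the preset correlation.

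The lower proximal tubule and higher injury transcripts in kidneys labelled DXZ were weighed first. A smaller share of proximal tubule alone, with the other segments kept in proportion, would raise the markers of all other segments alike. Yet the distal convoluted tubule list had a median log2 fold change of -0.55, with every DXZ score below every saline score, which argues against that as the whole cause. That median was -0.27 without saline 3 and -0.30 without saline 4, and its call held in both but not with an estimated correlation (adjusted p = 0.304). Principal cell genes, at a median of 0.53 that did not pass, go with a smaller share. Sampled pieces that differ in region need not change all other segments alike, so these values cannot decide for or against such a difference. With length and GC trends removed the proximal tubule median was -1.21 and both lists kept their calls under the preset correlation, which argues against those trends. With an estimated correlation and no trends removed neither list passed (adjusted p = 0.355 for both). If 1 library from each group had been exchanged, undoing it would restore the true groups, but the 12 splits that undo such an exchange gave at most 1 changed gene against 853, which argues against it, although they gave 5 to 21 lists against 13. DXZ 1 lay among or above the saline libraries in the thick ascending limb (0.18), endothelium (0.78) and NRF2 (-0.13) scores, but no saline library reached the scores of DXZ 2 or DXZ 3 in these, as a partner in an exchange would. An exchange of all labels between the groups would only turn the sign of the median of -1.16 and cannot be told apart from a difference between the treatments, since no library without cisplatin and no transcript that marks DXZ was used here; a real difference in injury also stays open.

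The macrophage score of DXZ 1 (1.30) lay above those of DXZ 2 and DXZ 3 (-0.67 and -1.14), with saline libraries between -0.50 and 0.65. Total counts of DXZ 1 differed from those of DXZ 2 and DXZ 3 by a log2 ratio of at most 0.107 and were lower than both, while its score led the higher of the others by 1.97. Scores were already scaled to library size, so this comparison could hardly have pointed to depth and is weak evidence against it. More vascular and stromal tissue in the DXZ 1 piece and less of it in the others cannot be told apart: DXZ 1 was above DXZ 2 and DXZ 3 in the endothelium score (0.78, -0.88 and -1.43), the pericyte and smooth muscle score (0.57, -0.70 and -0.76) and the matrix score (1.23, -0.37 and -1.08), but it led the highest saline library by 0.0899, 0.249 and 0.702 in these, and DXZ 2 and DXZ 3 lay below all saline libraries in the endothelium and pericyte scores. A different stage of inflammation or repair in these kidneys was not tested and stays open.

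Urothelial and squamous genes among the largest increases may come from more urothelium in the DXZ samples. The 5 uroplakin genes had a median log2 fold change of 1.90, but none had groups apart: Upk1b was at 9.30, 3.14 and 19.2 CPM in DXZ 1, 2 and 3 and at 8.80 CPM in saline 3. Of a list of 15 urothelial genes, 9 averaged at least 1 CPM in saline kidneys, 0 are in another list and 1 (Ivl) was named by the rule. The list passed camera (adjusted p = 7.53e-05, or 0.712 with an estimated correlation), but 1 of its 15 members, Ivl, passed by edgeR's test. Since the list was chosen after its values were seen and holds Ivl, its p-value is not independent support for more urothelium. Elf3 was at 46.1 and 77.8, Gata3 at 11.8 and 18.2 and Psca at 4.41 and 30.9 CPM in saline and DXZ (edgeR adjusted p = 0.118, 0.207 and 0.108), while Krt14 had a log2 fold change of -0.61 and Krt5, Krt15 and Grhl3 of 0.71, 0.53 and 0.49 (edgeR adjusted p between 0.713 and 0.837). In DXZ 2, where Upk1b was low, Slpi was at 85.1 and Sprr2f at 50.4 CPM, above their levels in DXZ 1 and DXZ 3. The uroplakin median was past the bound set for more urothelium, but the other condition set, groups apart for each uroplakin, was not met. Each uroplakin was above every saline library in DXZ 1 and DXZ 3, and below saline 3 in DXZ 2. Urothelium and a change within tubule cells therefore cannot be told apart.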
